A study of Homo sapiens with 45 samples.

How the data were processed

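Small RNA libraries of HCT116 cells and their knockout derivatives were made with TruSeq Small RNA kits from whole-cell RNA (8 groups) and from RNA immunoprecipitated with antibodies to AGO1, AGO2 or all AGO proteins (7 groups), with 3 biological replicates each. DROSHA knockout and siRNA samples of the series were not analysed here. The deposited files hold counts per RNA feature, 1 file per library, and per the labels were made by the authors with cutadapt 1.16 and Bowtie 1.1.2 against GRCh38 (hg38). The settings, and how reads matching several features were counted, are not given in the sources used here, so the counts of paralogs such as the let-7 members or miR-642a and miR-642b carry that uncertainty. Over all files there were 167112 features, 162398 of them Ensembl transcripts, and 2817 mature miRNAs after miRNA variant entries (1.11% of miRNA counts) were summed to their miRNA. The "hsa-" prefix of the miRNA names was dropped in the text. Positions were taken from GENCODE v29 on GRCh38, which held 95.4% of the Ensembl entries.

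Total counts per library ranged from 1783590 to 9860313. No molecular identifiers were reported, so PCR duplicates are counted as reads, and the intervals and floors cover counting error only. Counting intervals are exact, at the 95% level. For a miRNA with 0 counts in a group, the bound uses a floor of 3 counts over the group.

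miRNAs were tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr (minimum count 10, minimum total 15), TMM scaling on miRNA counts and the quasi-likelihood F test. The Benjamini-Hochberg adjusted p threshold was 0.05. There was 1 fit of the 24 whole-cell libraries, 1 of the 21 IP libraries and 1 of the 6 WT whole-cell and pan-AGO libraries, giving 17 comparisons. SE was taken as the size of the log2 fold change over the square root of F. The 16 miRNA lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over lists and comparisons. No call was kept with an estimated correlation. The lists were the let-7, miR-17-92, miR-200, miR-15/16, miR-30, miR-23/27/24 and miR-10, miR-99, miR-100 and miR-125 groups, colorectal cancer-associated, p53-responsive and Microprocessor-independent miRNAs, the 14q32 and C19MC clusters, and blood and serum, muscle and stroma, neural and pluripotent cell markers. Arm balance was tested with limma on log2 ratios of 5p to 3p counts (pseudocount 0.5) for hairpins with mean counts of at least 10 in the minor arm and 50 over both arms. The major arm of a hairpin was taken from the WT AGO2 IP for whole-cell RNA and from WT whole-cell RNA for the IPs. Shares were compared with exact permutation tests.

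Comparisons, tests, lists and the alternatives for the main results were fixed before the data were examined. The added alternatives were chosen after seeing the data: fits without variant entries, with the total of RNAs other than Ensembl transcripts, and on the miRNAs enriched in both AGO IPs, shares without Ensembl transcripts, shares of single abundant miRNAs, AGO2-bound shares under other scales, counts behind arm shares, simulated unrelated changes, arm balance in the IPs, major and minor arms, RNAs other than miRNA, and miR-200c and miR-141 in the pan-AGO IP. miRNAs were named by a rule fixed in advance. It took up to 10 rises and 10 falls for AGO1, AGO2, AGO1/2, AGO1/2/3 and TNRC6A/B KO against WT and up to 4 each way otherwise, at 20 CPM or more in a group and with groups that did not overlap (10% by chance for 3 against 3). It also took the 10 most abundant WT whole-cell miRNAs, up to 4 members per list and up to 3 hairpins each way. Alternatives included RLE factors, no TMM, the total of all counted RNAs, DESeq2 1.42.0, other count filters, 2-group fits, a replicate block and leaving out each library.

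Whether replicate numbers pair the libraries was checked by correlating residuals across miRNAs, which are not independent replicates. The correlations for the 3 numbers were 0.17, 0.324 and 0.304 for TNRC6A/B KO against TNRC6A KO, 0.185, 0.112 and 0.163 against TNRC6B KO, 0.392, 0.102 and 0.594 for the AGO1 IP, and 0.271, 0.176 and 0.147 for the AGO1 against the AGO2 IP. Only the first count moved by over 1.5 times with a replicate block, from 3 to 5. Tested on simulated data at these depths, edgeR recovered 31% of 2-fold and 97% of 4-fold changes for AGO1 KO against WT, and 11% and 60% for AGO1/2/3 KO against WT in the pan-AGO IP. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.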

Results

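Small RNAs were sequenced from HCT116 cells, a human colorectal carcinoma line, and from derivatives lacking Argonaute or TNRC6 proteins. Argonaute proteins (AGO1 to AGO4) bind miRNAs, and TNRC6 proteins (TNRC6A, TNRC6B) link Argonaute to mRNA repression. Whole-cell RNA came from wild-type (WT) cells and from knockout (KO) cells. The knockouts were of TNRC6A, of TNRC6B, of both (TNRC6A/B), of AGO1, of AGO2, of both (AGO1/2), and of these with AGO3 (AGO1/2/3). RNA bound to Argonaute came from immunoprecipitation (IP) with an AGO1 antibody in WT and AGO1 KO cells, an AGO2 antibody in WT and AGO2 KO cells, and a pan-AGO antibody in WT, AGO1/2 KO and AGO1/2/3 KO cells. Each of the 15 groups held 3 biological replicates, 45 libraries in all. The library descriptions number the replicates and name no clones. The spread may therefore be that between cultures of a single line. Differences between lines that do not come from the knockout cannot then be told apart from its effect. Total counts per library ranged from 1783590 to 9860313 and mature miRNA counts from 39851 to 7142721. Fold changes below are log2 values ± SE with n = 3 per group. Levels are CPM of miRNA totals multiplied by TMM factors, ± SD with n = 3, and are not shares of the miRNA counts. These factors ran from 0.117 to 0.133 in the AGO2 IP of WT and from 8.66 to 11.8 in the AGO1 IP of AGO1 KO. Levels from different fits are not on one scale. For every miRNA named for the size of its change, no library of one group lay within the range of the other.

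Fragments of the mRNAs of the targeted genes were read first as a check of the labels, as counts of the transcript with the most counts in each library. AGO1 fragments numbered 33, 24 and 17 counts in the WT whole-cell libraries, 11, 4 and 8 in AGO1 KO, 3, 3 and 5 in AGO1/2 KO and 1, 2 and 5 in AGO1/2/3 KO. In the pan-AGO IP, AGO1 fragments numbered 43, 56 and 58 counts in WT, 3, 4 and 3 in AGO1/2 KO and 3, 3 and 3 in AGO1/2/3 KO. AGO3 fragments numbered 31, 20 and 38 counts in WT whole-cell RNA, 39, 30 and 38 in AGO1/2 KO and 1, 9 and 4 in AGO1/2/3 KO. TNRC6B fragments numbered 33, 29 and 27 counts in WT, 6, 18 and 15 in TNRC6B KO and 16, 11 and 15 in TNRC6A/B KO. All these counts are not scaled to library depth, and ribosomal RNA took a larger part of the TNRC6 KO libraries, as given below. The lower TNRC6B counts therefore do not check the labels by themselves. For AGO2 (63, 77 and 93 counts in WT, 50, 24 and 64 in AGO2 KO, 93, 79 and 102 in AGO1/2 KO) and TNRC6A (15, 21 and 15 in WT, 5, 12 and 16 in TNRC6A KO, 10, 9 and 12 in TNRC6A/B KO) the fragments check nothing. The deleted part of each gene is not given in the sources used here, and fragments outside it remain.

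Mature miRNAs made up a smaller part of whole-cell small RNA in every Argonaute knockout. Their share was 5.25 ± 0.476% (SD, n = 3) of all counts in WT, 2.64 ± 0.334% in AGO1 KO, 3.69 ± 0.669% in AGO2 KO, 2.33 ± 0.158% in AGO1/2 KO and 1.74 ± 0.386% in AGO1/2/3 KO. The TNRC6 knockouts lay on the other side, at 9.32 ± 0.746% in TNRC6A KO, 7.87 ± 0.568% in TNRC6B KO and 10.1 ± 2.68% in TNRC6A/B KO. In the IPs the share was 17.4 ± 8.49% in WT against 1.7 ± 0.225% in AGO1 KO with the AGO1 antibody, and 81.8 ± 0.493% against 19.3 ± 3.66% in AGO2 KO with the AGO2 antibody. With the pan-AGO antibody it was 42.1 ± 12.9% in WT, 19.9 ± 6.19% in AGO1/2 KO and 8.21 ± 4.52% in AGO1/2/3 KO. None of these knockout groups overlapped its WT group, and each two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The 10 most abundant miRNAs of WT whole-cell RNA, led by let-7a-5p, let-7f-5p and miR-25-3p, held 47.2 ± 1.6% of miRNA counts in WT and 24.1 ± 3.91% in AGO1/2/3 KO.

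The scale of the counts moved the middle of the tested miRNAs, and with it the log2 fold changes below. With TMM, with the miRNA total alone and with the total of all counted RNAs their median was 0.22, 0.69 and -0.29 in AGO1 KO, 0.05, 0.25 and -0.26 in AGO2 KO, 0.23, 0.81 and -0.34 in AGO1/2 KO and 0.18, 1.32 and -0.30 in AGO1/2/3 KO. It was 0.07, -0.09 and 0.72 in TNRC6A KO, 0.03, -0.02 and 0.55 in TNRC6B KO and 0.07, -0.10 and 0.79 in TNRC6A/B KO. In the IPs it was -0.15, -3.08 and 0.13 for AGO1, -0.44, -3.18 and -1.17 for AGO2, -0.02, 0.999 and -0.05 for pan-AGO AGO1/2 KO and 0.01, 2.53 and 0.03 for pan-AGO AGO1/2/3 KO. For AGO1 against AGO2 it was 0.35, 3.52 and 1.24, and for pan-AGO against whole-cell RNA -0.19, -2.33 and 0.60.

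**Figure D1:**
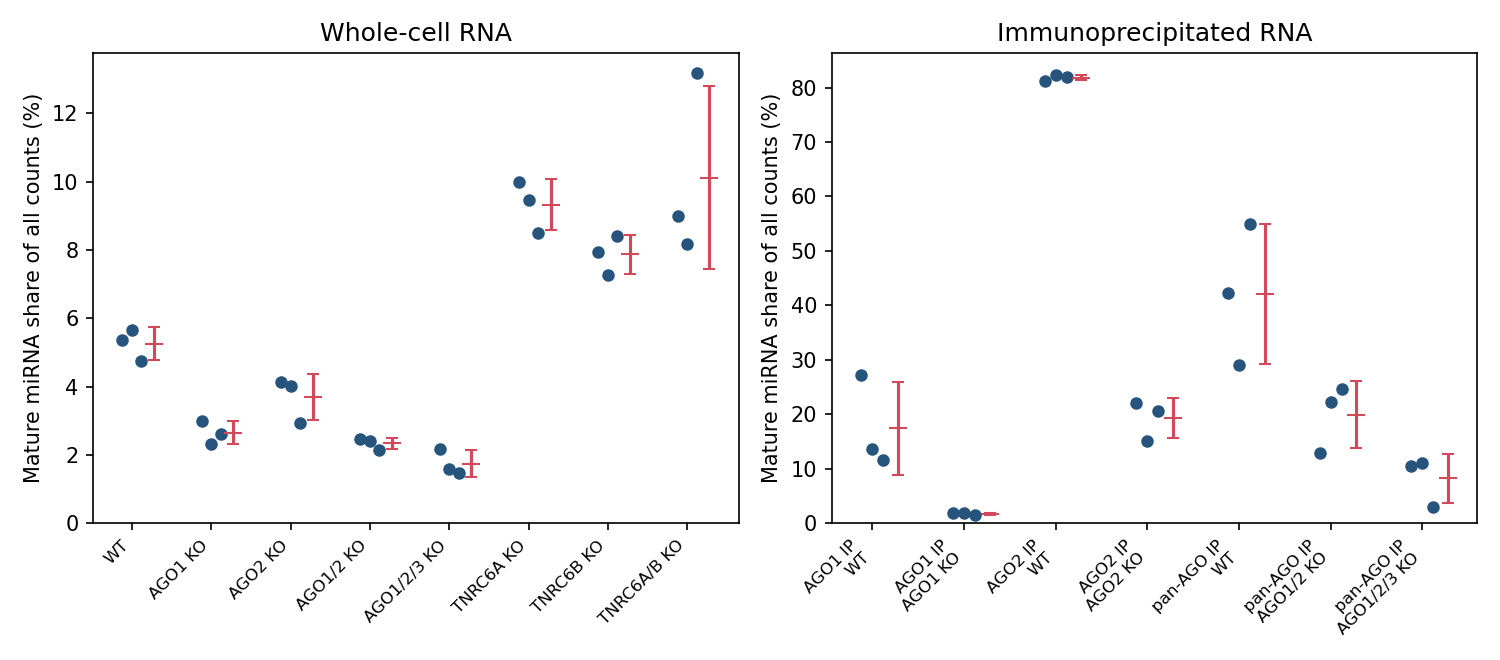
Share of mature miRNAs in all counts (%, y axis) per group; points are the 3 libraries of a group, and the bar with whiskers beside them is their mean ± SD. The 3 libraries of each knockout lie on one side of the WT libraries of the same material, below WT in the Argonaute knockouts and above it in the TNRC6 knockouts.

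Scaled by TMM, AGO1 KO whole-cell RNA held less of 63 of 274 tested miRNAs of an enriched set. The set held the miRNAs called higher, under TMM, in WT than in the matching knockout in both the AGO1 and the AGO2 IP. With the miRNA total alone, 114 of its 291 members were higher and 13 lower in the AGO1 IP. In the AGO2 IP 21 were then higher and 34 lower, so membership depends on the scale. Among the 63, miR-877-5p, a mirtron cut from an intron by splicing rather than by DROSHA, fell by 2.19 ± 0.33 (766 ± 159 against 3492 ± 734 CPM). Further falls among them were miR-99b-5p (-1.88 ± 0.31), miR-135b-5p (-2.34 ± 0.48), miR-326-3p (-2.01 ± 0.33), miR-3613-5p (-1.93 ± 0.41) and miR-30a-3p (-2.41 ± 0.43), and miR-550a-3p had 3 against 25 counts (ratio 8.49-fold, 2.59 to 43.9, counting interval). Outside the set, miR-21-3p, the partner strand of the growth-promoting miR-21-5p, fell by 2.92 ± 0.51 (466 ± 189 against 3551 ± 2073 CPM), next to miR-545-3p (-2.18 ± 0.38) and let-7i-3p (-1.93 ± 0.46). Rises were led by miRNAs at no more than 99.9 CPM in WT, miR-519b-5p (4.23 ± 0.57), miR-7703 (3.04 ± 0.60), miR-5694 (2.93 ± 0.49), miR-10522-5p (2.90 ± 0.51), miR-6859-5p (2.77 ± 0.54), miR-4746-5p (2.64 ± 0.42), miR-520b-5p (2.59 ± 0.40) and miR-1976 (2.55 ± 0.42), of which miR-519b-5p and miR-520b-5p belong to the placental C19MC cluster. With few counts, miR-3659-5p (18 against 1 counts, ratio 17.7-fold, 2.79 to 736) and miR-670-5p (26 against 3 counts, ratio 8.5-fold, 2.61 to 43.9) also rose. The let-7 family, which restrains growth genes, had 0 rises and 4 falls among 19 members (0 and 7 adjusted over the list alone, median log2 fold change -0.63, camera adjusted p = 1.28e-06, adjusted p = 0.297 with an estimated correlation). There let-7a-5p stood at -0.84 ± 0.34 and let-7b-5p at -1.02 ± 0.35, neither past the threshold. The miR-10, miR-99, miR-100 and miR-125 families had 0 rises and 3 falls among 13 members (0 and 6 adjusted over the list alone, median log2 fold change -0.89, camera adjusted p = 3.14e-06, adjusted p = 0.297 with an estimated correlation), with miR-125a-5p at -1.55 ± 0.34. The miR-23/27/24 clusters had 0 rises and 4 falls among 11 members (0 and 5 adjusted over the list alone, median log2 fold change -0.23, camera adjusted p = 0.000969, adjusted p = 0.297 with an estimated correlation), among them miR-23a-3p (-1.30 ± 0.33), miR-24-3p (-1.22 ± 0.35) and miR-23b-3p (-1.36 ± 0.34). Colorectal cancer-associated miRNAs gave 0 rises and 4 falls among 17 members (0 and 6 adjusted over the list alone, median log2 fold change -0.57, camera adjusted p = 1.09e-05, adjusted p = 0.297 with an estimated correlation), with miR-222-3p at -1.40 ± 0.36. Microprocessor-independent miRNAs had 1 rise and 8 falls among 27 members (1 and 10 adjusted over the list alone, median log2 fold change -0.16, camera adjusted p = 0.00189, adjusted p = 0.391 with an estimated correlation). The medians (rises/falls) with the miRNA total alone and with the total of all counted RNAs were -0.14 (0/2) and -1.15 (0/14) for let-7 and -0.42 (0/2) and -1.40 (0/8) for the miR-10, miR-99, miR-100 and miR-125 families. They were 0.26 (0/3) and -0.76 (0/5) for the miR-23/27/24 clusters, -0.10 (0/4) and -1.08 (0/9) for colorectal cancer-associated and 0.31 (3/3) and -0.66 (1/12) for Microprocessor-independent miRNAs. Of 291 miRNAs higher in WT than in the matching knockout in both the AGO1 and the AGO2 IP, 274 were tested, and 0 rose and 63 fell (median -0.68). AGO1 KO differed from WT in 206 of 1990 tested miRNAs, 130 higher and 76 lower, by edgeR's quasi-likelihood test. With counts scaled otherwise edgeR called 281 (249 higher, 32 lower) with the miRNA total alone and 292 (47 higher, 245 lower) with the total of all counted RNAs. In the enriched set 2 rose and 29 fell (median -0.21) with the miRNA total alone, and 0 rose and 164 fell (median -1.19) with the total of all counted RNAs. For AGO1 KO the count was 116 without WT replicate 1 and 94 without WT replicate 2. It was 138 (63 higher, 75 lower) without AGO1 KO replicate 2 and 143 (67 higher, 76 lower) without AGO1 KO replicate 3.

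Few miRNAs differed between AGO2 KO and WT whole-cell RNA. The largest falls with more than 3 counts per group were miR-1226-3p (-2.37 ± 0.40), miR-454-5p (-2.04 ± 0.45), miR-6511a-3p (-1.95 ± 0.40), miR-1229-3p (-1.85 ± 0.36), miR-421 (-1.82 ± 0.34), miR-3200-3p (-1.69 ± 0.36), miR-545-3p (-1.68 ± 0.38), let-7c-5p (-1.58 ± 0.36) and miR-1306-5p (-1.497 ± 0.33). Both miR-1226-3p and miR-1229-3p are mirtrons. With few counts too, miR-33b-5p, hosted by the sterol regulator SREBF1, had 1 against 19 counts (ratio 13.8-fold, 2.19 to 573, counting interval). The 4 rises were miR-519b-5p (2.63 ± 0.68), miR-520b-5p (1.81 ± 0.41), miR-4746-5p (1.66 ± 0.42) and miR-4523-3p (1.47 ± 0.37). The let-7 family had 0 rises and 2 falls among 19 members (2 and 3 adjusted over the list alone, median log2 fold change -0.28, camera adjusted p = 0.0309, adjusted p = 0.623 with an estimated correlation). Microprocessor-independent miRNAs had 0 rises and 3 falls among 27 members (0 and 4 adjusted over the list alone, median log2 fold change -0.19, camera adjusted p = 0.00192, adjusted p = 0.391 with an estimated correlation). Under those 2 totals the medians were -0.10 (0/2) and -0.61 (0/3) for let-7 and -0.02 (0/3) and -0.48 (0/4) for Microprocessor-independent miRNAs. In the enriched set 0 rose and 11 fell (median -0.34). There 0 rose and 9 fell (median -0.15) with the miRNA total alone, and 0 rose and 27 fell (median -0.65) with the total of all counted RNAs. AGO2 KO differed from WT in 16 of 1990 tested miRNAs, 4 higher and 12 lower, by edgeR. Other scales gave AGO2 KO 9 (0 higher, 9 lower) with the miRNA total alone and 34 (1 higher, 33 lower) with the total of all counted RNAs. For AGO2 KO the count was 7 without WT replicate 1 and 4 without WT replicate 2. Calls of AGO1 KO and AGO2 KO shared 3 higher miRNAs (0.261 for independent lists) and 8 lower ones (0.458). Changes were dealt out anew among miRNAs of like abundance and simulated against the same WT libraries in 20 runs. These gave shorter lists that shared 0.2 and 1.15 on average, where independent lists of that length would share 0.195 and 0.349. Part of the excess over independent lists may come from these shared controls or from changes kept within like abundance. The runs do not separate these. Data simulated without an effect shared 0 in each such pair, where they gave almost no calls to share (at most 0.3 on average).

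Set directly against AGO1 KO, AGO2 KO cells held more miR-21-3p (3.83 ± 0.53, 6672 ± 2639.7 against 466 ± 189 CPM), let-7i-3p (2.25 ± 0.47), miR-6075 (2.24 ± 0.49) and miR-18a-3p of the miR-17-92 cluster (2.19 ± 0.34). They held less miR-4688-5p (-2.98 ± 0.64), miR-6859-5p (-2.43 ± 0.56) and miR-139-5p (-2.25 ± 0.46), while miR-499b-3p had 3 against 31 counts (ratio 7.36-fold, 2.3 to 37.6). Between these knockouts edgeR called 49 of 1990 tested miRNAs, 26 higher and 23 lower. Other scales called 35 (13 higher, 22 lower) with the miRNA total alone and 60 (51 higher, 9 lower) with the total of all counted RNAs. Leaving out 1 library, the count was 31 without AGO1 KO replicate 2, 19 without AGO1 KO replicate 3, 23 without AGO2 KO replicate 1, 14 without AGO2 KO replicate 2 and 101 without AGO2 KO replicate 3.

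In cells lacking both AGO1 and AGO2, 48 of 136 abundant miRNAs (at least 1000 CPM in a group) fell and 14 rose. Among them miR-877-5p fell by 3.62 ± 0.36 (283 ± 39.4 against 3492 ± 734 CPM) and miR-99b-5p by 3.20 ± 0.33 (541 ± 72.3 against 4985 ± 194 CPM). Further falls were miR-3200-3p (-4.10 ± 0.47), miR-324-3p (-3.22 ± 0.38), miR-1226-3p (-3.19 ± 0.44), miR-744-5p (-3.10 ± 0.40), miR-1229-3p (-3.08 ± 0.41), miR-301a-3p (-3.03 ± 0.59) and miR-330-3p (-3.001 ± 0.42), and miR-548d-5p had 2 against 39 counts (ratio 11.9-fold, 3.08 to 102). The largest rises were miR-642a-3p (3.59 ± 0.34, 1019 ± 199.7 against 84.1 ± 9.81 CPM), cut from an intron of the incretin receptor gene GIPR. Others were miR-642b-3p (2.95 ± 0.45), miR-5011-5p (2.70 ± 0.67), miR-6817-3p (2.57 ± 0.62), miR-519b-5p (2.38 ± 0.71), miR-920 (2.31 ± 0.64), miR-629-3p (2.26 ± 0.34), miR-2054 (2.19 ± 0.36), miR-451b-5p (2.17 ± 0.41) and miR-5580-3p (2.11 ± 0.39). Among the 10 most abundant miRNAs, miR-25-3p (-1.27 ± 0.32), miR-191-5p (-1.70 ± 0.35), let-7d-5p (-1.79 ± 0.33) and miR-7-5p (-1.57 ± 0.29) fell, and let-7a-5p stood at -1.01 ± 0.34 without passing. The miR-17-92 and paralog clusters, which drive proliferation, had 2 rises and 8 falls among 23 members (2 and 10 adjusted over the list alone, median log2 fold change -0.85, camera adjusted p = 0.000251, adjusted p = 0.297 with an estimated correlation), with miR-93-5p at -2.60 ± 0.35. The miR-200 family, which represses the mesenchymal regulators ZEB1 and ZEB2, had 0 rises and 4 falls among 9 members (2 and 4 adjusted over the list alone, median log2 fold change -0.97, camera adjusted p = 0.00122, adjusted p = 0.347 with an estimated correlation), with miR-200c-3p (-2.18 ± 0.29) and miR-429 (-2.81 ± 0.37). The let-7 family gave 2 rises and 6 falls among 19 members (3 and 11 adjusted over the list alone, median log2 fold change -1.01, camera adjusted p = 2.31e-05, adjusted p = 0.347 with an estimated correlation). The miR-10, miR-99, miR-100 and miR-125 families had 0 rises and 6 falls among 13 members (0 and 6 adjusted over the list alone, median log2 fold change -0.42, camera adjusted p = 0.000202, adjusted p = 0.297 with an estimated correlation). Under the miRNA total alone and the total of all counted RNAs the medians were -0.25 (3/5) and -1.43 (2/11) for miR-17-92, -0.38 (3/3) and -1.55 (0/5) for miR-200, -0.42 (3/5) and -1.60 (0/12) for let-7 and 0.16 (2/6) and -1.02 (0/6) for the last list. The enriched set of 274 tested miRNAs had 2 rises and 107 falls (median -0.98). There 16 rose and 68 fell (median -0.39) with the miRNA total alone, and 1 rose and 177 fell (median -1.56) with the total of all counted RNAs. AGO1/2 KO differed from WT in 180 of 1990 tested miRNAs, 59 higher and 121 lower, by edgeR. Other scales gave AGO1/2 KO 403 (332 higher, 71 lower) with the miRNA total alone and 270 (16 higher, 254 lower) with the total of all counted RNAs. For AGO1/2 KO the count was 118 without AGO1/2 KO replicate 3.

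In AGO1/2/3 KO cells the largest fall was in miR-200c, an epithelial miRNA. Its main strand miR-200c-3p fell by 7.54 ± 0.39 (79.5 ± 17.3 against 14817 ± 1079 CPM; edgeR's quasi-likelihood test, adjusted p = 6.86e-19), and its partner miR-200c-5p had 2 against 119 counts (ratio 29.4-fold, 7.98 to 246, counting interval). The hairpin lies at chromosome 12, 6963699 to 6963766 (GRCh38) in an intron of MIR200CHG. Other falls were miR-744-5p (-4.98 ± 0.46), miR-532-3p (-4.91 ± 0.44), miR-877-5p (-4.91 ± 0.40) and miR-100-5p (-4.79 ± 0.46). With few counts, miR-106a-5p (2 against 318 counts, ratio 78.7-fold, 21.6 to 653), miR-3200-3p (2 against 314 counts, ratio 77.7-fold, 21.3 to 644) and miR-330-3p (3 against 201 counts, ratio 33.2-fold, 11.2 to 162) fell too, and miR-33b-5p (0 against 19 counts) was at least 3.13-fold lower. All 10 of the most abundant WT miRNAs fell relative to the middle of the tested miRNAs, among them let-7a-5p (-2.25 ± 0.35), let-7f-5p (-1.71 ± 0.31), let-7b-5p (-1.10 ± 0.35), let-7d-5p (-3.52 ± 0.36), miR-191-5p (-3.75 ± 0.38) and the growth-restraining miR-7-5p (-4.45 ± 0.33). As a share of miRNA counts 9 of the 10 were lower, and let-7b-5p held 3.72 ± 0.699% against 3.65 ± 0.445% in WT. Its fall did not pass without AGO1/2/3 KO replicate 2, without replicate 3 or without WT replicate 1. Rises were miR-486-3p (4.62 ± 0.75), miR-642a-3p (3.33 ± 0.34), miR-7703 (3.22 ± 0.63), miR-23b-5p (3.19 ± 0.33), miR-561-5p (2.99 ± 0.37), miR-6131 (2.82 ± 0.41), miR-4649-3p (2.69 ± 0.59), miR-548z (2.67 ± 0.36), miR-550a-3-5p (2.53 ± 0.59) and miR-642b-3p (2.49 ± 0.47), of which miR-486-3p comes from the erythroid gene ANK1.

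The miR-200 family had 0 rises and 8 falls among 9 members (0 and 8 adjusted over the list alone, median log2 fold change -3.01, camera adjusted p = 5.32e-13, adjusted p = 0.12 with an estimated correlation), with miR-429 at -4.16 ± 0.42 and miR-200b-3p at -2.78 ± 0.33. The let-7 family had 1 rise and 13 falls among 19 members (1 and 13 adjusted over the list alone, median log2 fold change -1.73, camera adjusted p = 5.82e-08, adjusted p = 0.297 with an estimated correlation). The miR-17-92 clusters had 2 rises and 14 falls among 23 members (2 and 14 adjusted over the list alone, median log2 fold change -2.12, camera adjusted p = 1.11e-06, adjusted p = 0.12 with an estimated correlation). Among these miR-93-5p fell by 4.45 ± 0.39 while its neighbour strand miR-25-5p rose by 2.31 ± 0.28. The miR-10, miR-99, miR-100 and miR-125 families had 0 rises and 7 falls among 13 members (0 and 7 adjusted over the list alone, median log2 fold change -1.27, camera adjusted p = 2.17e-05, adjusted p = 0.297 with an estimated correlation), with miR-125b-5p at -3.80 ± 0.45. Colorectal cancer-associated miRNAs had 0 rises and 10 falls among 17 members (2 and 10 adjusted over the list alone, median log2 fold change -1.46, camera adjusted p = 6.07e-05, adjusted p = 0.297 with an estimated correlation), with miR-31-5p (-1.81 ± 0.35), miR-21-5p (-1.45 ± 0.35) and miR-221-3p (-3.62 ± 0.39). Under the same 2 totals the medians were -1.89 (1/6) and -3.48 (0/8) for miR-200, -0.60 (4/9) and -2.19 (0/13) for let-7 and -0.97 (3/11) and -2.59 (2/14) for miR-17-92. They were -0.13 (3/6) and -1.72 (0/7) for the miR-10, miR-99, miR-100 and miR-125 families and -0.37 (5/6) and -1.90 (0/10) for colorectal cancer-associated miRNAs. Microprocessor-independent miRNAs gave 1 rise and 8 falls among 27 members (2 and 8 adjusted over the list alone, median log2 fold change -0.30, camera adjusted p = 0.0371, adjusted p = 0.537 with an estimated correlation). Neural markers had 0 rises and 3 falls among 7 members (0 and 3 adjusted over the list alone, median log2 fold change -0.77, camera adjusted p = 0.0426, adjusted p = 0.297 with an estimated correlation), led by miR-9-5p at -3.64 ± 0.49. With the miRNA total alone the medians of these 2 lists were 0.85 (13/4) and 0.37 (0/2). The miR-23/27/24 clusters had 4 rises and 5 falls among 11 members (4 and 5 adjusted over the list alone, median log2 fold change -0.90, camera adjusted p = 0.959), with miR-24-3p at -3.58 ± 0.39 and miR-23a-5p at 1.93 ± 0.34. There the sign of the camera test was up, that of the mean (-0.18) and the median down, and the median was 0.19 (5/3) with the miRNA total alone. Camera called none of the other 8 lists. These were miR-15/16 with 1 rise and 4 falls among 13 members (1 and 4 adjusted over the list alone, median -0.10), miR-30 with 2 rises and 2 falls among 11 members (2 and 2 adjusted over the list alone, median 0.62). The p53-responsive miRNAs had 0 rises and 1 fall among 9 members (0 and 1 adjusted over the list alone, median -0.77). The chromosome 14q32 cluster had 2 rises and 0 falls among 30 members (2 and 0 adjusted over the list alone, median 0.19), and C19MC 0 rises and 0 falls among 18 members (0 and 0 adjusted over the list alone, median 0.54). Blood and serum markers had 3 rises and 0 falls among 10 members (3 and 0 adjusted over the list alone, median 0.90). Muscle and stroma markers had 0 rises and 2 falls among 12 members (0 and 2 adjusted over the list alone, median -0.27). Pluripotent cell markers had 1 rise and 0 falls among 12 members (0 and 0 adjusted over the list alone, median 0.48). With the miRNA total alone the medians of miR-15/16, p53-responsive, and muscle and stroma markers were 1.05 (7/3), 0.37 (2/0) and 0.85 (3/1), and with the total of all counted RNAs that of 14q32 was -0.28 (1/1). Of the 274 tested miRNAs of the enriched set 10 rose and 170 fell (median -1.73). There 25 rose and 107 fell (median -0.58) with the miRNA total alone, and 5 rose and 205 fell (median -2.21) with the total of all counted RNAs. AGO1/2/3 KO differed from WT in 341 of 1990 tested miRNAs, 127 higher and 214 lower, by edgeR. Other scales gave AGO1/2/3 KO 985 (870 higher, 115 lower) with the miRNA total alone and 359 (44 higher, 315 lower) with the total of all counted RNAs. In a fit of the enriched set alone, relative to the middle of that set, let-7b-5p was called higher (0.71). There let-7f-5p stood at 0.10, miR-31-5p at 0.0123 and miR-21-5p at 0.36, none past the threshold. AGO1/2 KO and AGO1/2/3 KO shared 36 higher miRNAs (3.77 for independent lists) and 115 lower ones (13.01). Simulated unrelated changes against the same WT libraries gave shorter lists. They shared 3.8 and 38.6, where independent lists of that length would share 3.07 and 11.9. Part of the excess over independent lists may come from the shared WT libraries or from changes kept within like abundance. The runs do not separate these.

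**Figure D2:**
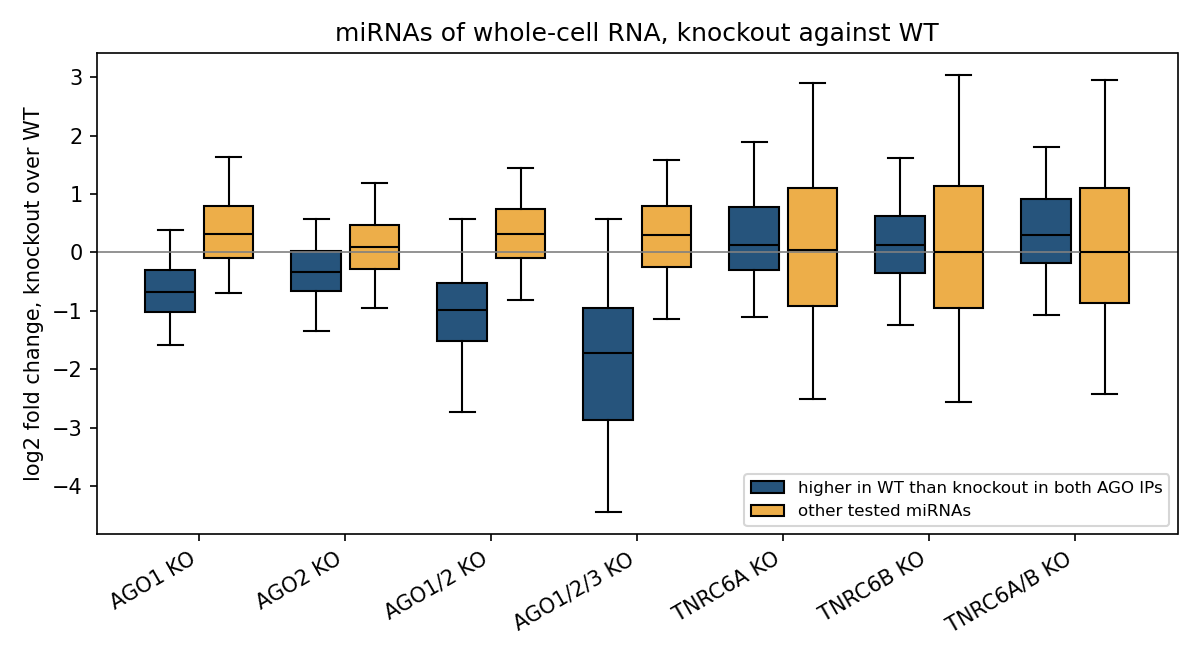
Log2 fold change in whole-cell RNA (y axis) per knockout against WT. The 274 tested miRNAs higher, under TMM, in WT than in the matching knockout in both AGO IPs stand beside the other tested miRNAs. Boxes span the quartiles, lines are medians and whiskers the 5th to 95th percentiles. The median of the enriched set is -0.68 in AGO1 KO, -0.98 in AGO1/2 KO and -1.73 in AGO1/2/3 KO.

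Cells lacking AGO3 in addition to AGO1 and AGO2 held less miR-200c and less miR-141-5p, from the neighbouring hairpin. Against AGO1/2 KO, miR-200c-3p fell by 5.36 ± 0.37 (79.5 ± 17.3 against 3261 ± 347 CPM) and miR-141-5p by 4.16 ± 0.53; miR-200c-5p had 2 against 128 counts (ratio 51.9-fold, 14.1 to 433) and miR-106a-5p 2 against 29 counts (ratio 11.7-fold, 2.97 to 102). Abundant miR-7-5p (-2.87 ± 0.31), miR-191-5p (-2.04 ± 0.36), let-7d-5p (-1.73 ± 0.34) and let-7g-5p (-1.65 ± 0.32) also fell. Higher were miR-30a-3p (3.17 ± 0.38), miR-4699-5p (2.20 ± 0.62), miR-6733-5p (2.07 ± 0.60) and miR-134-5p, a neuronal miRNA of the 14q32 cluster (1.72 ± 0.52). Against AGO1/2 KO, edgeR called 86 of 1990 tested miRNAs, 9 higher and 77 lower, and 96 (55 higher, 41 lower) with the miRNA total alone. Without 1 library the count was 49 without AGO1/2 KO replicate 1, 54 without AGO1/2 KO replicate 2, 34 without AGO1/2/3 KO replicate 2 and 50 without AGO1/2/3 KO replicate 3.

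**Figure D3:**
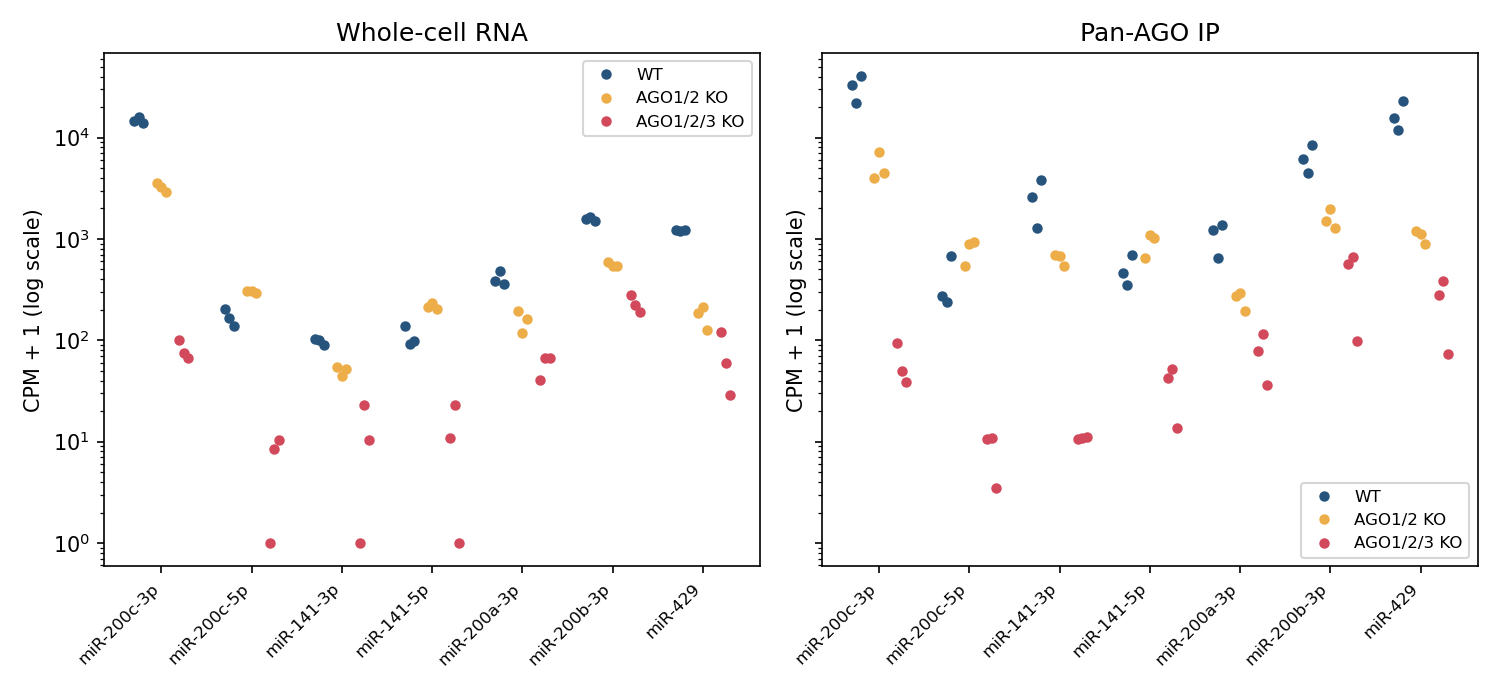
Levels of miR-200 family arms (CPM + 1, log scale, y axis) in WT, AGO1/2 KO and AGO1/2/3 KO; each point is 1 library, in whole-cell RNA (left) and in the pan-AGO IP (right). The miR-200c-3p level averaged 79.5 ± 17.3 against 3261 ± 347 CPM in AGO1/2/3 KO and AGO1/2 KO whole-cell RNA.

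The TNRC6 knockouts shared their largest rises and falls. Here miR-3684, in an intron of METAP1 (chromosome 4, 98997387 to 98997460, GRCh38), had 8956 against 1 counts in TNRC6A KO and WT (ratio 6943-fold, 1246 to 274253). It had 4328 against 1 counts in TNRC6B KO and WT (ratio 4087-fold, 733 to 161474) and 7981 against 1 counts in TNRC6A/B KO and WT (ratio 4894-fold, 878 to 193344). Likewise miR-5089-5p rose by 9.33 ± 0.51, 9.64 ± 0.52 and 9.29 ± 0.51 in the same order, and miR-4291 by 7.19 ± 0.62, 7.13 ± 0.62 and 7.03 ± 0.62. Also, miR-6863 was higher in TNRC6A KO (7.04 ± 0.46) and miR-5699-3p in TNRC6B KO (7.32 ± 0.55). Higher in TNRC6A/B KO were miR-6863 (6.86 ± 0.46), miR-5699-3p (6.76 ± 0.55), miR-3915 (5.99 ± 0.54), miR-6841-5p (5.89 ± 0.51) and miR-527-3p (5.795 ± 0.59), and miR-4420-5p (191 against 1 counts, ratio 117-fold, 20.8 to 4650.4) and miR-598-3p (127 against 1 counts, ratio 77.9-fold, 13.7 to 3100.2). Falls were led by miR-6787-5p, within the lactate transporter gene SLC16A3 (-7.05 ± 0.57, -6.78 ± 0.57 and -7.09 ± 0.57), and miR-5589-5p (-6.98 ± 0.60, -6.19 ± 0.57 and -6.63 ± 0.57). Also miR-3195 fell in TNRC6A KO (-5.62 ± 0.39) and TNRC6A/B KO (-5.14 ± 0.37), miR-563-5p in TNRC6B KO (-5.86 ± 0.63) and TNRC6A/B KO (-6.23 ± 0.62). Lower in TNRC6A/B KO were miR-5584-3p (-5.24 ± 0.57), miR-1225-3p (-4.999 ± 0.53), miR-1469 (-4.90 ± 0.43), miR-6131 (-4.69 ± 0.52) and miR-10396a-3p (-4.68 ± 0.53). Placental miR-520b-5p had 1 against 62 counts in TNRC6A KO and WT (ratio 80-fold, 13.8 to 3209) and 0 against 62 counts in TNRC6B KO and WT. It was at least 21.9-fold lower in TNRC6B KO and at least 33.7-fold lower in TNRC6A/B KO.

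Among the most abundant miRNAs in TNRC6A/B KO, miR-191-5p (1.01 ± 0.34) and miR-31-5p (0.85 ± 0.34) rose and miR-7-5p fell (-0.92 ± 0.28), while let-7a-5p (0.48 ± 0.34) and miR-25-3p (0.29 ± 0.32) did not pass. The tumour suppressor miR-34a-5p, induced by p53, rose by 1.79 ± 0.35, and p53-responsive miRNAs had 4 rises and 1 fall among 9 members (4 and 1 adjusted over the list alone, median log2 fold change 1.27, camera adjusted p = 0.422). Blood and serum markers had 6 rises and 0 falls among 10 members (6 and 0 adjusted over the list alone, median log2 fold change 1.30, camera adjusted p = 0.0426, adjusted p = 0.297 with an estimated correlation), among them miR-486-3p (5.51 ± 0.70), miR-144-5p (4.96 ± 0.57) and miR-122-5p (1.24 ± 0.34). Microprocessor-independent miRNAs had 2 rises and 10 falls among 27 members (2 and 10 adjusted over the list alone, median log2 fold change -0.26, camera adjusted p = 0.0354, adjusted p = 0.517 with an estimated correlation). The median of the latter was 0.41 (7/6) with the total of all counted RNAs. Muscle and stroma markers had 7 rises and 0 falls among 12 members (9 and 0 adjusted over the list alone, median log2 fold change 1.30, camera adjusted p = 0.0934). Under the 2 totals the medians were 1.2 (4/1) and 2.02 (7/1) for p53-responsive miRNAs, 1.20 (5/0) and 2.05 (7/0) for blood and 1.21 (3/0) and 2.06 (9/0) for muscle markers. The let-7 family had 2 rises and 1 fall among 19 members (2 and 1 adjusted over the list alone, median log2 fold change 0.12, camera adjusted p = 0.929), with a let-7 median of -0.22 (1/3) with the miRNA total alone. Of the enriched set, 72 rose and 26 fell (median 0.30). There 58 rose and 41 fell (median 0.09) with the miRNA total alone, and 162 rose and 6 fell (median 1.01) with the total of all counted RNAs. In TNRC6A KO 58 rose and 19 fell (median 0.12). There 48 rose and 31 fell (median -0.05) with the miRNA total alone, and 129 rose and 9 fell (median 0.77) with the total of all counted RNAs. TNRC6A KO differed from WT in 835 of 1990 tested miRNAs, 472 higher and 363 lower, by edgeR. TNRC6B KO differed in 842 of 1990 tested miRNAs, 473 higher and 369 lower, and TNRC6A/B KO in 874 of 1990 tested miRNAs, 495 higher and 379 lower. With the miRNA total alone these were 740 (352 higher, 388 lower), 737 (390 higher, 347 lower) and 818 (399 higher, 419 lower). With the total of all counted RNAs these were 951 (763 higher, 188 lower), 911 (695 higher, 216 lower) and 1026 (847 higher, 179 lower). TNRC6A KO and TNRC6B KO shared 409 higher miRNAs (112 for independent lists) and 302 lower ones (67.3). Simulated unrelated changes against the same WT libraries gave shorter lists, with 360 and 353 higher and 316 and 317 lower calls on average. They shared 124.65 and 103.8, where independent lists of that length would share 77.8 and 61.3. Part of the excess over independent lists may come from the shared WT libraries or from changes kept within like abundance. The runs do not separate these. Ribosomal RNA held 47.5 to 56.4% of counts in the TNRC6 knockout libraries against 15.02 to 39.66% in the other whole-cell libraries. No WT library of that composition was analysed here.

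TNRC6A/B KO exceeded TNRC6A KO in miR-224-5p (1.65 ± 0.34) and lay below it in miR-302b-3p (-2.55 ± 0.42) and miR-302a-5p (-1.97 ± 0.38), which mark pluripotent cells. Against TNRC6B KO it held more miR-4745-3p (2.48 ± 0.42), miR-6858-3p (2.38 ± 0.55), miR-486-5p (2.23 ± 0.53) and miR-6800-3p (1.83 ± 0.44) and less miR-1286-5p (-2.20 ± 0.38), miR-3941-5p (-1.64 ± 0.36), miR-448 (-1.54 ± 0.36) and miR-190b-3p (-1.42 ± 0.33). Against TNRC6A KO, edgeR called 3 of 1990 tested miRNAs, 1 higher and 2 lower, and 5 miRNAs with the replicate block. There 105 had an unadjusted p under 0.05 by edgeR, near the number chance gives. Another division of these libraries into groups of 3 gave more calls than the real one. Against TNRC6B KO edgeR called 12 of 1990 tested miRNAs, 7 higher and 5 lower, and 151 had an unadjusted p under 0.05. Under other scales the first was 2 (1 higher, 1 lower) with the miRNA total alone and the second 2 (2 higher, 0 lower) with the miRNA total alone and 19 (18 higher, 1 lower) with the total of all counted RNAs. The first count was 1 without TNRC6A KO replicate 1 and 6 without TNRC6A/B KO replicate 3; the second was 32 without TNRC6A/B KO replicate 2, 7 without TNRC6A/B KO replicate 3, 4 without TNRC6B KO replicate 1, 4 without TNRC6B KO replicate 2 and 5 without TNRC6B KO replicate 3.

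The AGO1 IP of WT cells held more of the abundant miRNAs than that of AGO1 KO cells. Here miR-7-1-3p was higher in WT by 8.20 ± 0.85 (17509.8 ± 6820.3 against 60.1 ± 35.5 CPM), and miR-130b-5p (7.88 ± 0.72), miR-30e-3p (7.86 ± 0.82) and miR-31-3p (7.53 ± 0.87) followed. All 10 of the most abundant whole-cell miRNAs were higher in WT, from let-7b-5p (3.61 ± 0.69) to miR-23a-3p (6.58 ± 0.79). Lower in WT were miR-7157-3p (-2.25 ± 0.51), miR-3059-3p (-1.82 ± 0.49), miR-8077-3p (-1.76 ± 0.46) and miR-4508 (-1.65 ± 0.48). The AGO1 IP of WT differed from that of AGO1 KO in 362 of 2632 tested miRNAs, 337 higher and 25 lower, by edgeR. Under other scales it was 2316 (124 higher, 2192 lower) with the miRNA total alone. The enriched set, defined with TMM, had a median of 3.78 there. Its median was 0.68 (114 higher, 13 lower) with the miRNA total alone and 4.10 (291 higher, 0 lower) with the total of all counted RNAs.

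Relative to the middle of the tested miRNAs, the AGO2 IP of WT cells held more of the abundant miRNAs than that of AGO2 KO cells. There let-7c-5p was higher in WT by 4.88 ± 0.66 (26280.3 ± 5783 against 891 ± 163 CPM), next to miR-7113-5p (5.26 ± 0.68), miR-7854-5p (4.97 ± 0.49) and miR-382-5p of the 14q32 cluster (4.84 ± 0.51). Of the 10 most abundant whole-cell miRNAs all were higher, from miR-7-5p (2.44 ± 0.69) to let-7a-5p (3.86 ± 0.75). As a share of miRNA counts, however, 6 of the 10 were lower in WT, among them miR-25-3p (6.04 ± 0.151% against 6.94 ± 0.33%). Lower were miR-486-3p (-4.70 ± 1.18), miR-3612 (-3.49 ± 0.51), miR-216a-5p (-3.40 ± 0.57) and miR-4502 (-3.39 ± 0.57). The AGO2 IP of WT differed from that of AGO2 KO in 1161 of 2632 tested miRNAs, 660 higher and 501 lower, by edgeR. Other scales gave the AGO2 IP 2114 (27 higher, 2087 lower) with the miRNA total alone and 1647 (447 higher, 1200 lower) with the total of all counted RNAs. With the miRNA total alone miR-7-5p stood at -0.37 there, and the enriched set had a median of -0.16 (21 higher, 34 lower) against 2.64 with TMM and 1.92 (235 higher, 0 lower) with the total of all counted RNAs.

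Compared with the AGO2 IP, the AGO1 IP of WT cells held less of 259 of the 291 enriched miRNAs, relative to the middle of the tested miRNAs. Lower in the AGO1 IP were miR-320a-5p (-7.12 ± 0.81), miR-200c-5p (-5.74 ± 0.76), miR-106b-3p (-5.70 ± 0.75) and miR-4761-5p (-5.40 ± 0.61), and let-7a-5p stood at -3.83 ± 0.74 and miR-21-5p at -3.55 ± 0.74. Higher were the low-level miR-670-5p (4.34 ± 0.81), miR-607 (3.99 ± 0.53), miR-4692 (3.84 ± 0.59) and miR-7849-5p (3.51 ± 0.60). By list, let-7 had 0 rises and 18 falls among 20 members (0 and 18 adjusted over the list alone, median log2 fold change -3.38, camera adjusted p = 5.82e-08, adjusted p = 0.297 with an estimated correlation). The miR-17-92 clusters had 2 rises and 20 falls among 28 members (2 and 20 adjusted over the list alone, median log2 fold change -3.35, camera adjusted p = 1.30e-06, adjusted p = 0.297 with an estimated correlation). The miR-200 family had 0 rises and 9 falls among 9 members (0 and 9 adjusted over the list alone, median log2 fold change -4.06, camera adjusted p = 7.15e-07, adjusted p = 0.297 with an estimated correlation). The C19MC cluster went the other way, 13 rises and 0 falls among 37 members (13 and 0 adjusted over the list alone, median log2 fold change 1.498, camera adjusted p = 0.00442, adjusted p = 0.297 with an estimated correlation), with miR-515-5p at 1.89 ± 0.48. With TMM, C19MC was not enriched over the matching knockout in either IP. Its median was -0.59 (0 higher, 1 lower) for AGO1 and -1.30 (0 higher, 10 lower) for AGO2. The higher C19MC level in the AGO1 IP therefore does not show binding to AGO1. The AGO1 and AGO2 IPs differed in 1202 of 2632 tested miRNAs, 532 higher and 670 lower, by edgeR. Under other scales it was 2196 (2146 higher, 50 lower) with the miRNA total alone and 1620 (1218 higher, 402 lower) with the total of all counted RNAs. In the enriched set 0 rose and 259 fell (median -2.77). The set had a median of 0.30 (93 higher, 30 lower) with the miRNA total alone. With the total of all counted RNAs it was -1.80 (4 higher, 197 lower). Under these 2 totals the medians (higher/lower) were -0.37 (3/3) and -2.42 (0/17) for let-7, -0.25 (8/9) and -2.39 (5/19) for miR-17-92, -0.79 (0/4) and -3.09 (0/9) for miR-200 and 4.4 (33/0) and 2.29 (23/0) for C19MC. Mature miRNAs were 17.4% of counts in the AGO1 IP and 81.8% in the AGO2 IP.

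The pan-AGO IP of WT cells was set against whole-cell RNA. There miR-21-5p, a growth-promoting miRNA raised in many carcinomas, was higher than in whole-cell RNA by 5.74 ± 0.38 (399909 ± 148160.0 against 7465 ± 435 CPM), next to miR-126-5p (5.85 ± 0.39), miR-141-3p (5.76 ± 0.46) and miR-374a-5p (5.75 ± 0.41). The precursor of miR-126 sits in an intron of the endothelial gene EGFL7. Lower were miR-5589-5p (-6.70 ± 0.52), miR-563-5p (-6.47 ± 0.55), miR-4497 (-6.25 ± 0.62) and miR-3648-3p (-6.24 ± 0.51). Among the most abundant whole-cell miRNAs, miR-23a-3p (3.03 ± 0.31), miR-25-3p (2.73 ± 0.33) and let-7f-5p (2.36 ± 0.32) were higher, and let-7d-5p stood at -0.17 ± 0.33 without passing. The enriched set had 234 members higher and 1 lower (median 2.30). Its median was 0.05 (104 higher, 83 lower) with the miRNA total alone and 3.11 (259 higher, 0 lower) with the total of all counted RNAs. Bound and whole-cell RNA differed in 993 of 1578 tested miRNAs, 473 higher and 520 lower, by edgeR. Under other scales it was 1251 (132 higher, 1119 lower) with the miRNA total alone and 967 (670 higher, 297 lower) with the total of all counted RNAs.

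In the pan-AGO IP of AGO1/2 KO cells, miR-642b-3p (4.44 ± 0.65), miR-550a-3-5p (4.06 ± 0.59), miR-642a-3p (3.83 ± 0.70) and miR-629-3p (3.21 ± 0.69) rose. Falls were miR-3200-3p (-4.59 ± 0.74), miR-1226-3p (-4.47 ± 0.66), miR-421 (-4.39 ± 0.57) and miR-1229-3p (-4.35 ± 0.56), the last at 48.1 ± 18.8 against 983 ± 252 CPM in AGO1/2 KO and WT. Abundant let-7a-5p was at -1.04 ± 0.67 and miR-23a-3p at -0.57 ± 0.62, neither past the threshold. In the enriched set, 291 tested, 0 rose and 142 fell (median -1.64). There 13 rose and 49 fell (median -0.49) with the miRNA total alone, and 0 rose and 129 fell (median -1.61) with the total of all counted RNAs. The AGO1/2 KO IP differed from WT in 274 of 2632 tested miRNAs, 43 higher and 231 lower, by edgeR. Another scale gave 347 (292 higher, 55 lower) with the miRNA total alone. For this IP the count was 175 without AGO1/2 KO replicate 1, 134 without AGO1/2 KO replicate 3 and 135 without WT replicate 3.

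In AGO1/2/3 KO the pan-AGO IP held less of the chromosome 12 pair, miR-200c-3p (-9.06 ± 0.87, 59.9 ± 29.3 against 31732 ± 9332 CPM) and miR-141-3p (-8.001 ± 0.78, 9.83 ± 0.216 against 2566 ± 1262 CPM), along with miR-1307-3p (-7.68 ± 1.15). At low counts, miR-937-3p had 1 against 598 counts (ratio 248-fold, 44.3 to 9799.9, counting interval). Rises were miR-3122 (3.31 ± 0.42), miR-889-3p (3.31 ± 0.48), miR-1199-3p (3.23 ± 0.47) and miR-3144-5p (3.13 ± 0.48). Abundant let-7a-5p (-2.98 ± 0.72), let-7d-5p (-4.40 ± 0.82), miR-191-5p (-4.48 ± 0.79) and miR-7-5p (-3.53 ± 0.73) fell, and let-7b-5p stood at -1.49 ± 0.64 without passing. Of the enriched set 1 rose and 257 fell (median -3.37). There 26 rose and 124 fell (median -0.86) with the miRNA total alone, and 1 rose and 246 fell (median -3.27) with the total of all counted RNAs. The AGO1/2/3 KO IP differed from WT in 704 of 2632 tested miRNAs, 235 higher and 469 lower, by edgeR. Another scale called 1827 (1688 higher, 139 lower) with the miRNA total alone. In a fit of the enriched set alone let-7a-5p stood at 0.14. Whole-cell RNA and the pan-AGO IP, which share no libraries, had 44 higher miRNAs in common (13.2 for independent lists) and 186 lower ones (43.8).

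Hairpins can yield a miRNA from their 5p or 3p arm, and the balance was tested for each. Where an arm had at most 10 counts in a group, the 5p and 3p counts of that group, the first or second of the 2, follow with the exact 95% interval of their pooled share. In AGO1/2/3 KO the 5p share of miR-328 (94 ± 1.74% against 33.2 ± 8.84%), miR-25 (23.6 ± 4.57% against 1.32 ± 0.053%) and miR-301a (66.7 ± 28.9% against 5.92 ± 3.52%, 8 and 5 counts in the first, interval 31.6 to 86.1%) rose. That of miR-186 (43.7 ± 15.1% against 97.2 ± 0.331%), miR-185 (69.4 ± 14.3% against 97.7 ± 0.887%) and miR-345 (16.7 ± 11.5% against 79.6 ± 2.99%, 5 and 25 counts in the first, interval 5.64 to 34.7%) fell. In AGO1/2 KO it rose for miR-23b (15.8 ± 2.22% against 2.05 ± 0.245%), miR-331 (27.4 ± 15.3% against 4.11 ± 1.61%) and miR-1229 (82.2 ± 5.1% against 35 ± 4.58%). It fell for miR-186 (80.2 ± 2.82% against 97.2 ± 0.331%), miR-642a (27 ± 4.4% against 74.5 ± 4.18%) and miR-4747 (4.89 ± 5.35% against 19.2 ± 4.72%, 10 and 211 counts in the first, interval 2.19 to 8.16%). In AGO1 KO the changed hairpins included miR-3615 (97.6 ± 1.18% against 81.8 ± 2.91%), miR-3648 (78.2 ± 1.59% against 45.7 ± 1.48%), miR-3940 (63.9 ± 6.01% against 29.7 ± 6.73%), with higher 5p shares. Lower ones were those of miR-3928 (82.9 ± 8.34% against 96 ± 1.7%), miR-135b (40.4 ± 16% against 75.6 ± 1.2%) and miR-3613 (11.8 ± 2.84% against 36.5 ± 8.51%). In AGO2 KO they were miR-1229 (64.2 ± 2.47% against 35 ± 4.58%) and miR-629 (61.1 ± 3.23% against 82.1 ± 4.69%). In TNRC6A/B KO they included miR-5584 (80.2 ± 5.75% against 5.1 ± 3.8%), miR-4467 (62.9 ± 13% against 14.9 ± 6.51%), miR-624 (34.5 ± 13.9% against 6.34 ± 2.26%), miR-5699 (5.1 ± 2.7% against 78 ± 17.2%, 37 and 9 counts in the second, interval 66.1 to 90.6%), miR-663a (64.7 ± 5.03% against 98.7 ± 0.406%) and miR-6891 (6.72 ± 3.29% against 73.1 ± 6.03%). The limma test of log2 arm ratios called 66 of 147 hairpins in AGO1/2 KO, 59 toward the minor arm, and 91 in AGO1/2/3 KO, 81 toward the minor arm, with the major arm taken from libraries outside the comparison. It called 19 in AGO1 KO (15 toward the minor arm), 2 in AGO2 KO, 67 in TNRC6A KO (30), 57 in TNRC6B KO (28) and 60 in TNRC6A/B KO (26). In AGO1 KO the count was 9 without AGO1 KO replicate 2, 10 without replicate 3, 11 without WT replicate 1 and 9 without WT replicate 2. In AGO2 KO it was 0 without AGO2 KO replicate 1, 7 without replicate 2, 0 without WT replicate 2 and 1 without WT replicate 3.

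Arm balance in bound RNA was tested after the data were seen. In the pan-AGO IP of AGO1/2 KO the 5p share rose for miR-1229 (69.9 ± 9.44% against 6.66 ± 3.54%), miR-937 (44.3 ± 17.6% against 4.29 ± 2.72%) and miR-200c (13.4 ± 3.44% against 1.18 ± 0.423%). It fell for miR-660 (93.4 ± 0.839% against 99.4 ± 0.313%), miR-486 (32.4 ± 12.2% against 80.6 ± 14.5%) and miR-642b (30.5 ± 2.74% against 78.3 ± 16.2%). In AGO1/2/3 KO it rose for miR-10401 (72.4 ± 24% against 1.41 ± 0.444%, 18 and 7 counts in the first, interval 50.6 to 87.9%), miR-937 (96.3 ± 6.42% against 4.29 ± 2.72%, 19 and 1 counts in the first, interval 75.1 to 99.9%) and miR-1229 (90.3 ± 4.51% against 6.66 ± 3.54%). It fell for miR-3613 (4.73 ± 5.4% against 81 ± 3.97%, 10 and 237 counts in the first, interval 1.96 to 7.32%), miR-660 (64.3 ± 15.7% against 99.4 ± 0.313%) and miR-186 (60.8 ± 13.4% against 99.1 ± 0.281%). Between the AGO1 and AGO2 IPs of WT cells, miR-19a (23.3 ± 8.88% against 0.537 ± 0.0887%), miR-1303 (86.3 ± 10.9% against 26.9 ± 2.24%) and miR-3648 (64 ± 10.7% against 9.55 ± 2.6%) leaned to 5p in the AGO1 IP. Leaning to 3p were miR-4747 (1.83 ± 1.64% against 43.3 ± 1.32%), miR-196a (98.2 ± 1.09% against 100 ± 0.0149%) and miR-1468 (51.6 ± 11.8% against 97.8 ± 0.723%). The limma test called 81 of 221 hairpins in the AGO1/2 KO IP (53 toward the minor arm), 135 in the AGO1/2/3 KO IP (88) and 88 between the AGO1 and AGO2 IPs (45); the first was 47 without WT replicate 3.

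**Figure D4:**
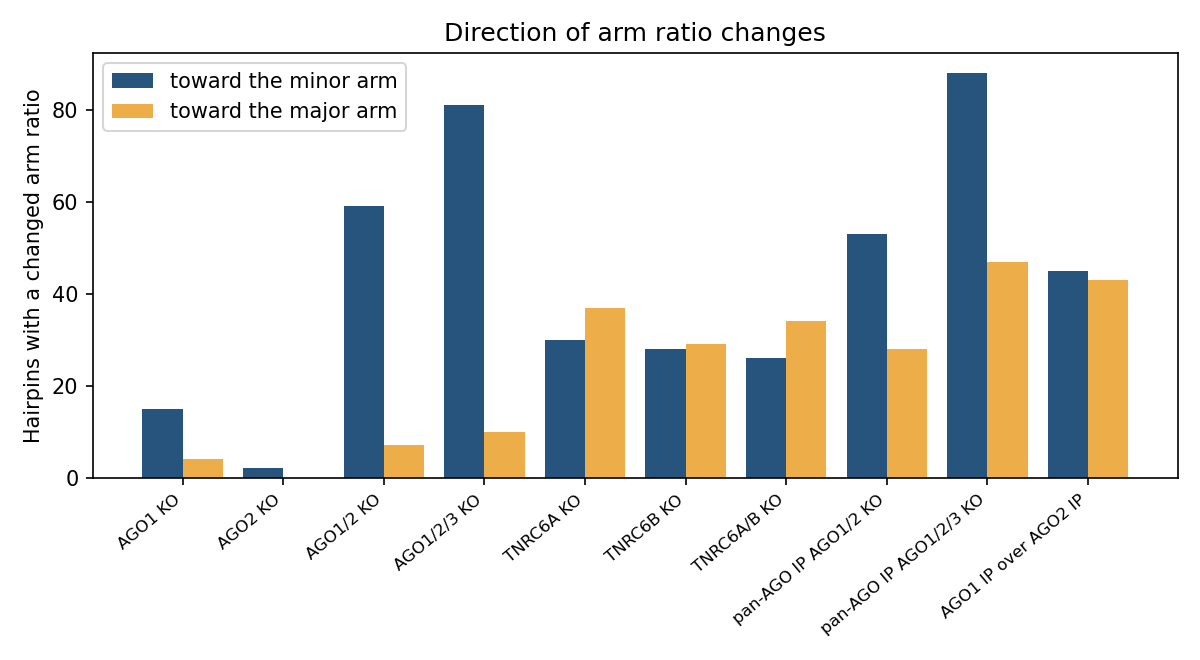
Number of hairpins with a changed arm ratio (y axis) per comparison, split by direction toward the minor or the major arm. In whole-cell RNA of AGO1/2/3 KO 81 hairpins moved toward the minor arm and 10 toward the major arm.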

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

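Of the tests in this part, the one of AGO2-bound shares in the TNRC6 knockouts and the splits of the samples were set before their results were seen, and the other tests were chosen after.

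The change in AGO1/2 KO differed between the pan-AGO IP and whole-cell RNA for 9 of 1515 miRNAs by an edgeR interaction test, 1 more positive and 8 more negative in the IP. For AGO1/2/3 KO the number was 98, 37 more positive and 61 more negative. In 100 splits of the samples, the real one included, 7 gave at least 9 calls (highest other 80) and 7 gave at least 98 (highest other 397). Labels were redrawn within each material, and each of the other 6 in both cases kept the true labels of 1 material, so it carried the knockout effect of that material. In the 85 splits that mixed the labels of both materials the highest count was 0 in both cases, so none of these gave as many calls as the real one. They put knockout and WT libraries into 1 group, which widens its spread and lowers the calls. A count of 0 there therefore does not measure how many calls chance gives, and the splits leave that open.

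RNAs outside the miRNA comparisons gave a signal above the knockout controls: 40 of 13085 were higher in WT than in the knockout in both the AGO1 and the AGO2 IP, where independent lists would share 2.15. They included 14 tRNA entries and 9 miRNA precursor entries. Reads in the precursor entries may be those of mature miRNAs. Some tRNA entries are gene copies, such as Leu-CAG-1-4 and Leu-CAG-1-5, and may hold the same reads. The 40 are therefore not independent of each other, and the 2.15 is only a rough yardstick. edgeR called 72 in the AGO1 IP and 479 in the AGO2 IP. For the AGO1 IP 3 of 10 splits gave as many calls (highest other 475), so the real split does not stand out there. The cause was not tested. For the AGO2 IP the highest other was 0. Without 1 library the number shared was 26 (AGO1 KO replicate 1), 19 (AGO1 KO replicate 3), 67 (AGO1 IP WT replicate 3), 24, 22 and 25 (AGO2 KO replicates 1, 2 and 3) or 23, 25 and 25 (AGO2 IP WT replicates 1, 2 and 3).

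Of the 127 miRNAs that rose in AGO1/2/3 KO whole-cell RNA, 44 were called higher also with the total of all counted RNAs, which argues against a scale set by the middle of the miRNAs as the whole cause for these. For the other 83 the median log2 fold change was 1.33 (SD 0.32) and 0.86 (SD 0.31) with that total, so a share set by the scale cannot be told apart from a smaller rise. Among 126 risen miRNAs tested in the AGO2 IP 15.9% were higher in WT than in AGO2 KO (exact 95% interval 9.97 to 23.4%), against 28.1% of all tested and 84.04% of 213 fallen ones. With RLE size factors for the AGO2 IP these were 16.7% (10.6 to 24.3%) of the risen, 28.7% of all tested and 84% of the fallen, and with the total of all counted RNAs 9.52% (5.02 to 16%) of the risen, 19% of all tested and 68.5% of the fallen. By the miRNA total alone they were 0.794% (0.0201 to 4.34%) of the risen, 1.34% of all tested and 9.39% of the fallen, and the interval of the risen then holds the share of all tested. As a source of part of the rises, fragments counted as miRNA but not bound to AGO2 therefore cannot be told apart from bound miRNA, and a response of the cells stays open, untested.

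The TNRC6 knockouts may differ from WT through a library batch. Descriptions of the WT and Argonaute KO whole-cell libraries begin with IN, and those of the TNRC6 KO libraries with A, AB or B. The labels do not say whether the libraries were prepared together. TNRC6A/B KO differed from TNRC6A KO in 3 miRNAs (5 with the replicate block; 1 without TNRC6A KO replicate 1 and 6 without TNRC6A/B KO replicate 3). It differed from TNRC6B KO in 12 (32 without TNRC6A/B KO replicate 2, 7 without TNRC6A/B KO replicate 3, 4 without TNRC6B KO replicate 1, 4 without TNRC6B KO replicate 2 and 5 without TNRC6B KO replicate 3). Similar effects of the knockouts would give few differences too. No WT library known to share their preparation was analysed here, so batch and knockout cannot be told apart. Of 489 risen miRNAs 27.8% were higher in WT in the AGO2 IP (exact 95% interval 23.9 to 32.01%), near the 28.1% of all tested, which leaves unbound fragments open, and 16.2% of 370 fallen ones were. Under the miRNA total alone for that IP these were 1.02% (0.333 to 2.37%) of the risen, 1.34% of all tested and 0% of the fallen, and with the total of all counted RNAs 20.4% (17 to 24.3%) of the risen, 19% of all tested and 8.11% of the fallen.

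In the pan-AGO IP of AGO1/2/3 KO against AGO1/2 KO, the log2 ratios of both arms together were -6.49 for miR-200c and -5.11 for miR-141 (both chosen for their falls). The median of the other 219 hairpins was -1.39 (SD 1.14). Of 221 hairpins ranked by this ratio, miR-200c had rank 1 and miR-141 rank 2. Hairpins chosen as the most changed lie far from the rest under any cause. These values therefore do not decide on a fall shared by all hairpins. All 4 arms were called lower, but as they were chosen for falling, lower output of both hairpins of the chromosome 12 locus stays open. PHB2 nearby had 122 counts, which argues against a deletion on every copy that reaches PHB2; its whole-cell counts were 4 against 26 in AGO1/2 KO, and the host MIR200CHG had 0 against 7 in the IP, so a smaller deletion, or one on some copies, stays open. Hypotheses of a biological cause, such as an effect of losing AGO3, were not tested.

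With 3 against 3 libraries the 10 splits are too few for a share under 0.05. The other splits mix libraries of both groups, which widens the spread within a group and lowers the calls. A low count there therefore does not measure how many calls chance gives. Real count and highest other were 206 and 0 for AGO1 KO, 16 and 0 for AGO2 KO, 180 and 0 for AGO1/2 KO, 341 and 19 for AGO1/2/3 KO, 835 and 1 for TNRC6A KO, 842 and 0 for TNRC6B KO, and 874 and 0 for TNRC6A/B KO. They were 49 and 6 for AGO2 KO against AGO1 KO, 86 and 2 for AGO1/2/3 KO against AGO1/2 KO, 3 and 7 for TNRC6A/B KO against TNRC6A KO, and 12 and 11 against TNRC6B KO. In the IPs they were 362 and 29 for AGO1, 1161 and 0 for AGO2, 274 and 2 for pan-AGO AGO1/2 KO, 704 and 0 for pan-AGO AGO1/2/3 KO, 1202 and 0 for AGO1 against AGO2, and 993 and 0 for pan-AGO against whole-cell RNA. For arm balance they were 19 and 0, 2 and 2, 66 and 0, 91 and 1, 67 and 0, 57 and 0, and 60 and 0 in the order of the first sentence of counts, then 81 and 1, 135 and 3, and 88 and 0 in the pan-AGO and AGO1 against AGO2 IPs. For list tests they were 40 and 26.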

How the results depend on the processing

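The alternatives limited to miRNAs enriched in both AGO IPs, without Ensembl transcripts or without variant entries, those of arm balance in the IPs, and other scales for the AGO2-bound shares were chosen after the results were seen. There were 6300 alternative values. Values of named miRNAs kept direction and side of the threshold in 3696, lost the threshold in 240, gained it in 31 and changed sign in 7. For list tests these were 1170, 68, 42 and 0, and for named hairpins 349 were kept and 14 lost the threshold. The cause was not tested where none is given.

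A mean of at least 100 counts tested fewer miRNAs and gave 173 for AGO1 IP against AGO2 IP, WT, 186 for AGO1 IP, WT against AGO1 KO, 62 for AGO1 KO against WT, 119 for AGO1/2 KO against WT, 148 for AGO1/2/3 KO against WT, 136 for AGO2 IP, WT against AGO2 KO, 26 for AGO2 KO against AGO1 KO, 120 for TNRC6A KO against WT, 1 for TNRC6A/B KO against TNRC6A KO, 2 for TNRC6A/B KO against TNRC6B KO, 128 for TNRC6A/B KO against WT, 111 for TNRC6B KO against WT, 231 for pan-AGO IP against whole-cell RNA, WT, 166 for pan-AGO IP, AGO1/2 KO against WT and 234 for pan-AGO IP, AGO1/2/3 KO against WT. Only enriched miRNAs, again fewer tested, gave 133 for AGO1 IP against AGO2 IP, WT, 15 for AGO1 KO against WT, 77 for AGO1/2 KO against WT, 130 for AGO1/2/3 KO against WT, 26 for AGO2 KO against AGO1 KO, 25 for AGO2 KO against WT, 98 for TNRC6A KO against WT, 28 for TNRC6A/B KO against TNRC6B KO, 100 for TNRC6A/B KO against WT, 79 for TNRC6B KO against WT, 191 for pan-AGO IP against whole-cell RNA, WT, 94 for pan-AGO IP, AGO1/2 KO against WT and 129 for pan-AGO IP, AGO1/2/3 KO against WT. In that fit the log2 fold changes in AGO1/2/3 KO were 0.36 for miR-21-5p, 0.0123 for miR-31-5p, 0.71 for let-7b-5p and 0.10 for let-7f-5p, and that of let-7a-5p in the pan-AGO IP of AGO1/2/3 KO 0.14, since its scale is the middle of the enriched miRNAs. The miRNA total alone gave 2196 for AGO1 IP against AGO2 IP, WT, 2316 for AGO1 IP, WT against AGO1 KO, 403 for AGO1/2 KO against WT, 985 for AGO1/2/3 KO against WT, 2114 for AGO2 IP, WT against AGO2 KO, 9 for AGO2 KO against WT, 2 for TNRC6A/B KO against TNRC6B KO and 1827 for pan-AGO IP, AGO1/2/3 KO against WT, miR-7-5p was at -0.37 in the AGO2 IP and let-7b-5p at 0.0421 in AGO1/2/3 KO. The total of all counted RNAs gave 34 for AGO2 KO against WT and 19 for TNRC6A/B KO against TNRC6B KO. Without Ensembl transcripts it gave 1936 for AGO1 IP against AGO2 IP, WT, 1834 for AGO2 IP, WT against AGO2 KO, 32 for AGO2 KO against WT and 19 for TNRC6A/B KO against TNRC6B KO. DESeq2 called 75 for AGO2 KO against AGO1 KO, 41 for AGO2 KO against WT and 5 for TNRC6A/B KO against TNRC6A KO. Fits of only 2 groups, with fewer libraries, called 334 for AGO1 KO against WT, 334 for AGO1/2 KO against WT, 7 for AGO2 KO against AGO1 KO, 0 for TNRC6A/B KO against TNRC6A KO, 2 for TNRC6A/B KO against TNRC6B KO and 533 for TNRC6A/B KO against WT. The 0 by edgeR there stands beside 49 of 1437 at an unadjusted p under 0.05 in that fit, where chance gives 71.85. The replicate block gave 5 for TNRC6A/B KO against TNRC6A KO and moved no other count by over 1.5 times. Over all lists and comparisons camera made 40 calls, and 0 with an estimated correlation. The fry test, which asks another question, made 66. A minor arm mean of at least 50 counts left 41 hairpins and gave 1 for AGO1 KO against WT, 24 for AGO1/2 KO against WT, 30 for AGO1/2/3 KO against WT, 0 for AGO2 KO against WT, 25 for TNRC6A KO against WT, 20 for TNRC6A/B KO against WT and 21 for TNRC6B KO against WT. A pseudocount of 5 gave 32 for AGO1 KO against WT and 6 for AGO2 KO against WT. The top-10 share difference, in percentage points, turned to -8.95 for AGO1/2 KO against WT, pan-AGO IP, -0.645 for TNRC6A KO against WT, -1.82 for TNRC6A/B KO against WT and -2.19 for TNRC6B KO against WT with the top 50, to -2.9 for AGO1/2 KO against WT, pan-AGO IP with each library's own 10, to -1.71 without TNRC6A/B KO replicate 3 and to 2.84 without pan-AGO AGO1/2/3 KO replicate 3.

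Leaving out 1 library, counts of changed miRNAs ranged from 918 to 1331 for AGO1 IP against AGO2 IP, WT, 307 to 402 for AGO1 IP, WT against AGO1 KO, 94 to 186 for AGO1 KO against WT, 118 to 155 for AGO1/2 KO against WT, 34 to 84 for AGO1/2/3 KO against AGO1/2 KO, 254 to 320 for AGO1/2/3 KO against WT, 859 to 1080 for AGO2 IP, WT against AGO2 KO, 14 to 101 for AGO2 KO against AGO1 KO, 4 to 20 for AGO2 KO against WT, 701 to 772 for TNRC6A KO against WT, 1 to 6 for TNRC6A/B KO against TNRC6A KO, 4 to 32 for TNRC6A/B KO against TNRC6B KO, 734 to 920 for TNRC6A/B KO against WT, 725 to 775 for TNRC6B KO against WT, 678 to 952 for pan-AGO IP against whole-cell RNA, WT, 134 to 335 for pan-AGO IP, AGO1/2 KO against WT and 510 to 725 for pan-AGO IP, AGO1/2/3 KO against WT. Changed hairpins ranged from 9 to 22 for AGO1 KO against WT, 55 to 63 for AGO1/2 KO against WT, 82 to 93 for AGO1/2/3 KO against WT, 0 to 7 for AGO2 KO against WT, 51 to 61 for TNRC6A KO against WT, 46 to 55 for TNRC6A/B KO against WT and 46 to 50 for TNRC6B KO against WT. List tests ranged from 36 to 41. The miRNA share difference in points ranged from -18.7 to -10.8 for AGO1 KO against WT, AGO1 IP, -2.87 to -2.4 for AGO1 KO against WT, -28.7 to -15.8 for AGO1/2 KO against WT, pan-AGO IP, -3.18 to -2.71 for AGO1/2 KO against WT, -40.4 to -27.5 for AGO1/2/3 KO against WT, pan-AGO IP, -3.77 to -3.31 for AGO1/2/3 KO against WT, -64 to -60.5 for AGO2 KO against WT, AGO2 IP, -1.82 to -1.18 for AGO2 KO against WT, 3.74 to 4.47 for TNRC6A KO against WT, 3.33 to 5.83 for TNRC6A/B KO against WT and 2.35 to 2.91 for TNRC6B KO against WT. Without Ensembl transcripts it was -32.5 for the AGO1 IP, and in TNRC6A, TNRC6B and TNRC6A/B KO 6.45, 4.62 and 8. Without the most abundant other RNA these were 6.79, 4.46 and 7.34. The top-10 share difference ranged from -32.9 to -27 for AGO1 KO against WT, AGO1 IP, -10.4 to -8.04 for AGO1 KO against WT, 1.5 to 5.24 for AGO1/2 KO against WT, pan-AGO IP, -10.8 to -8.94 for AGO1/2 KO against WT, -6.27 to 2.84 for AGO1/2/3 KO against WT, pan-AGO IP, -25.2 to -21.6 for AGO1/2/3 KO against WT, -15.1 to -12.1 for AGO2 KO against WT, AGO2 IP, -6.25 to -1.2 for AGO2 KO against WT, 1.82 to 3.41 for TNRC6A KO against WT, -1.71 to 5.57 for TNRC6A/B KO against WT and 1.6 to 3.19 for TNRC6B KO against WT. The smallest library, in the AGO1 IP of AGO1 KO, held 39851 miRNA counts, and recovery was not simulated for that comparison. In the 7 simulated ones edgeR recovered 60 to 97% of 4-fold changes.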

Other observations

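The tests in this part were chosen after the results were seen. Among RNAs other than miRNA, SCARNA15 and ACA33, guide RNAs for modification of other RNAs, were higher in WT than in the knockout in both the AGO1 IP (5.68 and 4.12 on the log2 scale) and the AGO2 IP (4.24 and 3.13). The precursor entries of mir-182, mir-21, mir-222, mir-423, mir-425, mir-574, mir-7-1, mir-7-2 and mir-93 were higher in both too. Of 94 tested precursor entries, 9 were higher in the AGO1 IP and 71 in the AGO2 IP. Their reads may be those of mature miRNAs, so binding of precursors is not shown. Of the 40 RNAs, 25 were lower in the pan-AGO IP of AGO1/2 KO and 35 in that of AGO1/2/3 KO, and TM4SF18 was higher.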
